A study of Homo sapiens with 12 samples.

How the data were processed

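Gene expression was measured by RNA sequencing in 12 libraries of 2 human cell lines held in a chip device: HCCLM3, a line of hepatoma cells, and LX2, a line of hepatic stellate cells. Each line was grown alone or with the other line, which gives 4 groups of 3 libraries. Groups were taken from the labels of treatment and cell line, and libraries are named by group and replicate number. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. How the lines were parted before RNA was extracted is not given in the sources used here.

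Per the labels' protocols, polyadenylated RNA was selected from total RNA and sequenced from both ends. The protocol speaks of adipose RNA, which is neither line, and the series text and the protocol name different Illumina sequencers. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used, with no role given, and the build named is mm8, a mouse build. The gene identifiers in the deposited tables are human. Of 60612 identifiers, 58394 were in GENCODE release 29, and 90.6% of these had the same chromosome and the same start or end there, so the coordinates of the tables, printed here, were taken as GRCh38 positions. Whether reads were counted by strand is not given in the sources used here.

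Per the file headers, the authors deposited raw counts and FPKM values (fragment counts scaled by gene length and library size) side by side for each library, in 1 table per line. The table of HCCLM3 held 60612 genes and that of LX2 held 32507, each of the latter with at least 1 count in an LX2 library. Every row named a gene, and no measured column was left without a sample. A count of 0 stood as an FPKM of 0.0001 in the HCCLM3 table and as 0 in the LX2 table, and was read here as an FPKM of 0. The deposited FPKM values summed to 313710 to 335480 per library in the table of HCCLM3 and to 266772 to 271937 in that of LX2, and how they were scaled across tables is not given in the sources used here, so levels set across the lines are a description only, and tests were made within a line or between changes within each line. The authors' raw count per gene was the unit of the tests, and FPKM means ± SD (n = 3) describe levels.

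Before the data were examined the test set down was limma on log2(FPKM + 1), with the edgeR quasi-likelihood test in its place should raw counts be present. They were, so edgeR 4.0.16 was used (R 4.3.3): genes were kept by filterByExpr (minimum count 10, minimum total 15), library sizes scaled by TMM, and co-cultured libraries compared with libraries alone in a fit per line. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The difference between lines, (HCCLM3 with LX2 minus HCCLM3 alone) minus (LX2 with HCCLM3 minus LX2 alone), was fitted over all 12 libraries. There were 35 gene lists fixed before the data were examined, with 802 different genes, of which each had an identifier in the tables. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with Benjamini-Hochberg adjustment over lists. The test with a correlation estimated per list stands beside it. Adjusted p-values of genes are from the edgeR quasi-likelihood test unless another tool is named.

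The genes named per line were fixed by rule: the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap and whose higher group had a mean FPKM of at least 5, up to 3 members of each list with the smallest p, and 9 genes named in advance (ALB, APOA1, COL1A1, COL1A2, ACTA2, VIM, TGFB1, VEGFA and MKI67). For the difference between lines they were the 8 genes with the smallest p and a mean FPKM of at least 5 in 1 group. Non-overlap of 3 against 3 libraries arises by chance in 10% of genes. Transcripts of the partner line were measured over genes with at least 20 FPKM in the partner alone and under 0.1 FPKM in the line itself alone, as the rise in co-culture in percent of the partner's level. A fold against a group whose libraries were all at 0 is a lower bound, with 3 counts over the group as the floor. Ratios with few counts carry exact 95% intervals from the binomial distribution, which cover counting error only (SciPy 1.17.1; Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3).

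The procedure was tested on simulated counts drawn from the means and sizes of the real libraries. Genes to be changed were drawn only from those with a mean count well above the filter's minimum, so recovery at low counts was not tested. Of genes changed 1.5-fold, 2-fold and 4-fold, 5.97%, 46.3% and 75.8% were recovered for HCCLM3 (17371 genes), 20.9%, 67.2% and 90.9% for LX2 (19082 genes), and 1.49%, 23.9% and 74.2% for the difference (20697 genes). False calls were 8 of 95 in HCCLM3, 11 of 134 in LX2 and 2 of 68 in the difference, so in both lines the share of false calls in the simulation (8.42% and 8.21%) was above the 0.05 set. None of 20 unchanged lists was called by camera in either line. Simulated genes were drawn independently of each other, so this does not test lists whose members move together. In HCCLM3 the estimated correlation within a list reached 0.55, for cytosolic ribosomal proteins. Far fewer genes were changed in the simulation than were called in the data, which makes the adjusted threshold stricter. The recovery is therefore no estimate for the data. The alternatives tried were limma on FPKM with other pseudocounts (0.1 and 0.01), other filters, scalings, variance models and thresholds, a block for the replicate number, DESeq2 1.42.0, and each library left out in turn.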

Results

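The 12 libraries held 68088914 to 77712308 counts in HCCLM3 alone, 65675929 to 68178411 in HCCLM3 with LX2, 61836616 to 65314354 in LX2 alone and 64438991 to 69891842 in LX2 with HCCLM3. In the library with the fewest counts, a gene with no count may stand at up to 0.0485 CPM (3 counts). The mitochondrial genome gave 7.98% ± 0.445 (SD, n = 3) of counts in HCCLM3 alone, 7.48% ± 0.628 in HCCLM3 with LX2, 6.74% ± 0.0573 in LX2 alone and 7.02% ± 0.0764 in LX2 with HCCLM3. Replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 39.5 to 99.4), so none was merged with another. Separate preparations of 1 culture also exceed counting noise, so it does not show that the replicates are independent.

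Grown alone, the lines carried different marker genes. The keratin KRT8 stood at 555 ± 29.2 FPKM (SD, n = 3) in HCCLM3 and 2.94 ± 0.0896 FPKM in LX2, and vimentin (VIM) at 2.08 ± 1.11 FPKM in HCCLM3 and 176 ± 18.7 FPKM in LX2, levels from separate tables. Of 30 hepatocyte markers, 9 reached 1 FPKM in HCCLM3 alone and 3 in LX2 alone. Albumin (ALB) stood at 0.531 ± 0.134 FPKM in HCCLM3. Of 27 stellate cell and fibroblast markers, 12 reached 1 FPKM in LX2 alone and 6 in HCCLM3 alone, while 3 and 4 reached 10 FPKM. LUM had 2798, 2921 and 2062 counts in HCCLM3 alone and 240, 174 and 213 in LX2 alone, and COL6A3 stood at 2.40 ± 0.369 FPKM in HCCLM3. In LX2 alone the collagen gene COL1A1 stood at 2.72 ± 0.0390 FPKM, while COL1A2, COL6A3 and SPARC had 0 counts in each library. With these markers at 0, whether LX2 is a stellate line was not settled here, and the name is that of the labels. Of 18 hepatoma and progenitor markers, 9 reached 1 FPKM in HCCLM3 alone and 9 in LX2 alone. In HCCLM3 alone AFP, a member of that list, stood at a mean of 0.718 FPKM. CEACAM6, AGR2 and CDH17, on neither the hepatocyte nor the hepatoma list, stood there at means of 376, 211 and 43.6 FPKM. Whether HCCLM3 is a hepatoma line was therefore not settled here either, and its name too is that of the labels.

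The first comparison asked how growth with LX2 changed HCCLM3. In HCCLM3 with LX2, the lists of hepatocyte markers, NF-kB targets, cytokines and the hypoxia response were higher by camera, and those of heat shock, cholesterol synthesis and mitosis were lower. None of these list calls held with an estimated correlation. That correlation was under the preset 0.01 for hepatocyte markers (-0.011), cytokines (-0.040) and cholesterol synthesis (-0.029). In those lists the lost call is no sign of members that move together. For NF-kB targets, the hypoxia response, heat shock and mitosis it was above the preset. The fibrinogen beta chain gene FGB (ENSG00000171564, chromosome 4, 154563011 to 154572807) stood at 2.16 ± 0.0196 FPKM alone and 33.4 ± 0.647 FPKM in co-culture (SD, n = 3; log2 fold change 3.79, SE 0.074; edgeR adjusted p = 6.67e-06), a 13.8-fold rise. CA9 (ENSG00000107159, chromosome 9, 35673918 to 35681159), a carbonic anhydrase induced by low oxygen, rose 33.2-fold from 0.554 ± 0.185 FPKM (log2 fold change 5.05). DAG1 (ENSG00000173402, chromosome 3, 49468703 to 49535618), which encodes dystroglycan, fell 7.46-fold, from 56.2 ± 6.56 to 8.45 ± 2.76 FPKM.

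Of 18045 genes tested in HCCLM3, 1829 rose and 2095 fell, 3924 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Leaving out single libraries gave 1971 to 3067 genes in all. Among the 1093 with an absolute log2 fold change of at least 1, the balance turned, with 828 up and 265 down. Genes with a count numbered 21261 to 21667 per library alone and 22734 to 23329 in co-culture. Transcripts of blood cells, described below, appeared in the co-cultured libraries, and their part in the large rises was not tested. On library totals without TMM factors, 2977 rose and 1039 fell. That scaling put the median log2 fold change of all tested genes at 0.21, against 0.033 with TMM, and changes are given relative to TMM. With limma on log2(FPKM + 1), 2320 rose and 1120 fell.

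Of the hepatocyte markers, 8 of 22 tested members rose and 0 fell (adjusted over the list alone, 9 and 3): FGG (4.31), FGB (3.79), FGA (1.92) and ALB (2.46) rose, with log2 fold changes in parentheses (camera adjusted p = 1.54e-09; adjusted p = 0.0672 with an estimated correlation). ALB went from 0.531 ± 0.134 to 3.34 ± 0.237 FPKM, and APOA1 had a log2 fold change of -0.24 (edgeR adjusted p = 0.822). Of the NF-kB targets, 11 of 21 tested members rose and 1 fell (adjusted over the list alone, 14 and 1), among them LCN2 (3.96), CXCL2 (2.07) and ICAM1 (0.78) (camera adjusted p = 3.85e-09; adjusted p = 0.0705 with an estimated correlation). LCN2, which encodes the iron-carrier binding protein lipocalin 2, went from 2.64 ± 0.548 to 46.2 ± 1.86 FPKM (399, 300 and 411 counts alone and 5535, 6156 and 6009 in co-culture). In the same libraries granulocyte precursor genes, a list added after seeing the data, went from 4 to 3477 counts over the group. Whether the rises of NF-kB targets and cytokines are tied to these transcripts was not tested. Each co-cultured library held more counts of LCN2 than that list had over the group. Of the cytokines and chemokines, 7 of 22 tested members rose and 1 fell (adjusted over the list alone, 9 and 1): TNFSF10 (3.74) and CXCL2 (2.07) rose and IL18 (-1.29) fell (camera adjusted p = 0.00142; adjusted p = 0.0705 with an estimated correlation). Of the type I interferon response genes, 6 of 23 tested members rose and 3 fell (adjusted over the list alone, 12 and 4), with BST2 (2.20) and MX1 (1.41) up and DDX58 (-1.66) down (camera adjusted p = 0.0498; adjusted p = 0.318 with an estimated correlation).

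Of the hypoxia response genes, 10 of 28 tested members rose and 3 fell (adjusted over the list alone, 12 and 3) (camera adjusted p = 3.85e-09; adjusted p = 0.0705 with an estimated correlation). Besides CA9, ANGPTL4 (3.47), VEGFA (2.32) and DDIT4 (2.13) rose, and the glucose transporter gene SLC2A1 (-0.96) fell. Of the angiogenesis factors, 7 of 19 tested members rose and 1 fell (adjusted over the list alone, 8 and 2), with VEGFA and ANGPTL4 among the rises and EPHA2 (-0.76) the fall (camera adjusted p = 0.00177; adjusted p = 0.132 with an estimated correlation). Of the ATF4 and amino acid response genes, 9 of 25 tested members rose and 3 fell (adjusted over the list alone, 9 and 3): NUPR1 (2.41), DDIT4 (2.13) and DDIT3 (1.32) rose and the amino acid transporter gene SLC7A5 (-1.08) fell (camera adjusted p = 0.00143; adjusted p = 0.0705 with an estimated correlation). Of the extracellular matrix genes, 10 of 32 tested members rose and 2 fell (adjusted over the list alone, 11 and 4): LOX (2.63), FN1 (1.24) and NID1 (1.13) rose and LAMA4 (-0.93) fell (camera adjusted p = 0.00177; adjusted p = 0.433 with an estimated correlation). The collagen genes COL1A1 and COL1A2 had 16, 20 and 541 and 0, 0 and 502 counts in the 3 libraries alone and 21, 356 and 1448 and 0, 320 and 853 counts in the 3 co-cultured libraries, and neither passed (edgeR adjusted p = 0.556 and 0.764). COL3A1 passed, with 58, 39 and 112 counts alone and 300, 848 and 1011 in co-culture (log2 fold change 3.30, edgeR adjusted p = 0.0106).

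Of the heat shock genes, 1 of 19 tested members rose and 13 fell (adjusted over the list alone, 1 and 13); HSP90AA1 (-1.63), HSPA4 (-0.89) and HSPA8 (-0.78) fell (camera adjusted p = 2.77e-09; adjusted p = 0.0705 with an estimated correlation). HSP90AA1, a chaperone gene, went from 416 ± 12.2 to 150.2 ± 9.53 FPKM. Of the cholesterol synthesis and uptake genes, 1 of 24 tested members rose and 10 fell (adjusted over the list alone, 1 and 12), with HMGCS1 (-1.87), SQLE (-0.86), CYP51A1 (-0.70) and NSDHL (-0.57) down (camera adjusted p = 0.00309; adjusted p = 0.0860 with an estimated correlation). Without HCCLM3 with LX2 replicate 2 the call of HMGCS1 was lost. Of the NRF2 targets, 1 of 25 tested members rose and 9 fell (adjusted over the list alone, 2 and 11), led by AKR1B10 (-0.93), SRXN1 (-0.58) and FTH1 (-0.59) (camera adjusted p = 0.00143; adjusted p = 0.0705 with an estimated correlation).

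Of the mitosis genes, 4 of 32 tested members rose and 12 fell (adjusted over the list alone, 4 and 14): CENPF (-1.31), DLGAP5 (-0.82) and TTK (-0.65) fell (camera adjusted p = 0.00309; adjusted p = 0.135 with an estimated correlation). MKI67 fell from 12.2 ± 4.15 to 5.91 ± 1.26 FPKM (log2 fold change -1.21), a call that was lost when single libraries were left out. Of the DNA replication genes, 2 of 32 tested members rose and 10 fell (adjusted over the list alone, 3 and 11), with CDT1 (-0.54) and RRM1 (-0.46) down and RFC5 (0.36) up (camera adjusted p = 0.0312; adjusted p = 0.135 with an estimated correlation). Of the growth factors and ligands, 5 of 27 tested members rose and 9 fell (adjusted over the list alone, 6 and 9): EREG (-1.72), AREG (-1.39) and INHBB (-1.22) and TGFB1 (-0.58) fell (camera adjusted p = 0.00834; adjusted p = 0.147 with an estimated correlation). The median of that list was -0.13. Of the immediate early genes, 4 of 26 tested members rose and 9 fell (adjusted over the list alone, 4 and 11), with EGR1 (-1.35) and FOS (-1.20) down and NR4A1 (1.53) up (camera adjusted p = 0.00996; adjusted p = 0.105 with an estimated correlation). Of the actin cytoskeleton genes, 1 of 29 tested members rose and 10 fell (adjusted over the list alone, 1 and 11): ZYX (-0.89) and FLNA (-0.89) fell and CNN3 (0.99) rose (camera adjusted p = 0.00538; adjusted p = 0.0874 with an estimated correlation).

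Markers of other cell types also moved in HCCLM3. Of the endothelial markers, 0 of 5 tested members rose and 2 fell (adjusted over the list alone, 1 and 3), namely ESAM (-1.43) and KDR (-1.02) (camera adjusted p = 0.0171; adjusted p = 0.139 with an estimated correlation). Of the leukocyte markers, 4 of 9 tested members rose and 0 fell (adjusted over the list alone, 4 and 0) (camera adjusted p = 0.000500; adjusted p = 0.0705 with an estimated correlation). LYZ, which encodes lysozyme, rose 8.17-fold from 0.546 ± 0.153 to 5.06 ± 0.751 FPKM, and LAPTM5 was at 0 in each library alone and at least 84.9-fold higher over the co-cultured group. Of the 8 largest rises, 7 were genes of blood cells or lay at the beta-globin locus. Over each group, the count ratio of HBB (ENSG00000244734, chromosome 11, 5225464 to 5229395) was 2581 (95% exact interval 1008 to 9473), that of HBA1 2095 (716 to 10160) and that of HBA2 1965 (672 to 9531). HBA1 and HBA2 are near-identical copies and may share reads. HBG2 was at least 587-fold higher over the group, S100A9 at least 266-fold and IGKC at least 338-fold. AC104389 (ENSG00000284931), at least 339.7-fold higher, overlaps HBG1 and HBG2 on the same strand and cannot be told from them by counts. IGKC had 24, 510 and 382 counts in the 3 co-cultured libraries, and its call was lost when single libraries were left out.

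**Figure D1:**
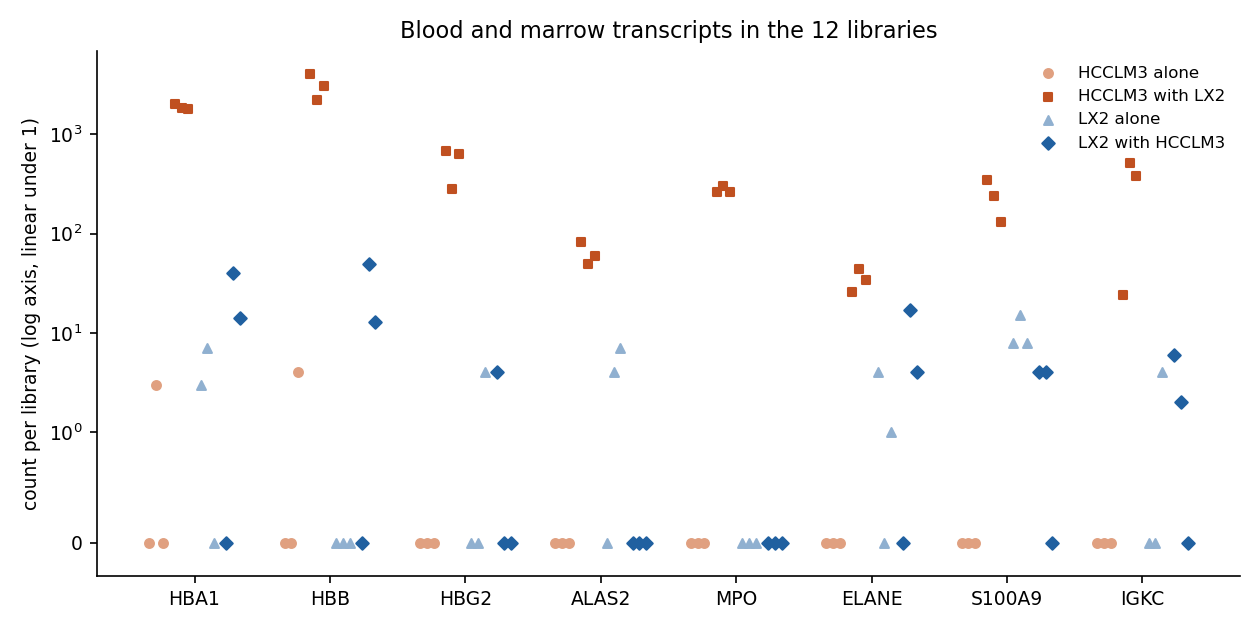
Counts per library, on an axis that is logarithmic above 1 and linear below, of 8 blood and marrow genes in the 12 libraries, 1 point per library with a symbol per group. HBB had 4038, 2211 and 3070 counts in HCCLM3 with LX2, against 0, 0 and 4 in HCCLM3 alone and 0, 49 and 13 in LX2 with HCCLM3.

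The other large falls in HCCLM3 were FGFBP1 (-2.73), CEACAM5 (-2.29), DHRS9 (-2.11) and UPK1B (-1.87) and AL162582 (ENSG00000230234; -1.85). FGFBP1 encodes a carrier protein of fibroblast growth factors and CEACAM5 the carcinoembryonic antigen. UGT1A3, which shares exons with other UGT1A genes, was at 7.07 ± 7.93 FPKM alone and 0.172 ± 0.0370 FPKM in co-culture, and its counts are uncertain. Of the other lists, p53 targets, glycolysis, hepatoma and progenitor markers, stellate cell and fibroblast markers and mitochondrially encoded genes did not pass (camera adjusted p = 0.157, 0.137, 0.164, 0.200 and 0.0523). Among their members, TP53INP1 (3.13), CDKN1A (0.74) and SLC16A3 (0.57) rose and KRT19 (-0.88), SPP1 (-0.59) and MT-CO1 (-0.62) fell. For p53 targets the median was -0.077 while mean and test pointed up. For glycolysis the mean was 0.0077 and for hepatoma and progenitor markers the median 0.050, while both tests pointed down. The median was opposite in sign to the test for oxidative phosphorylation and the unfolded protein response, and the mean for YAP targets (0.063, 0.069 and 0.013, the tests down). The remaining lists did not pass in HCCLM3 (camera adjusted p): stemness genes 0.0903, TGF-beta response 0.234, YAP targets 0.351, cytosolic ribosomal proteins 0.479, replication-dependent histones 0.479, epithelial genes 0.617, integrins and adhesion receptors 0.730, mesenchymal genes 0.881, fatty acid and triglyceride metabolism 0.929, matrix proteases and inhibitors 0.929, oxidative phosphorylation 0.929, unfolded protein response 0.967. In all, 18 of 35 lists passed in HCCLM3, and with an estimated correlation 0 did. With fry, which tests a list by itself, 20 passed.

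**Figure D2:**
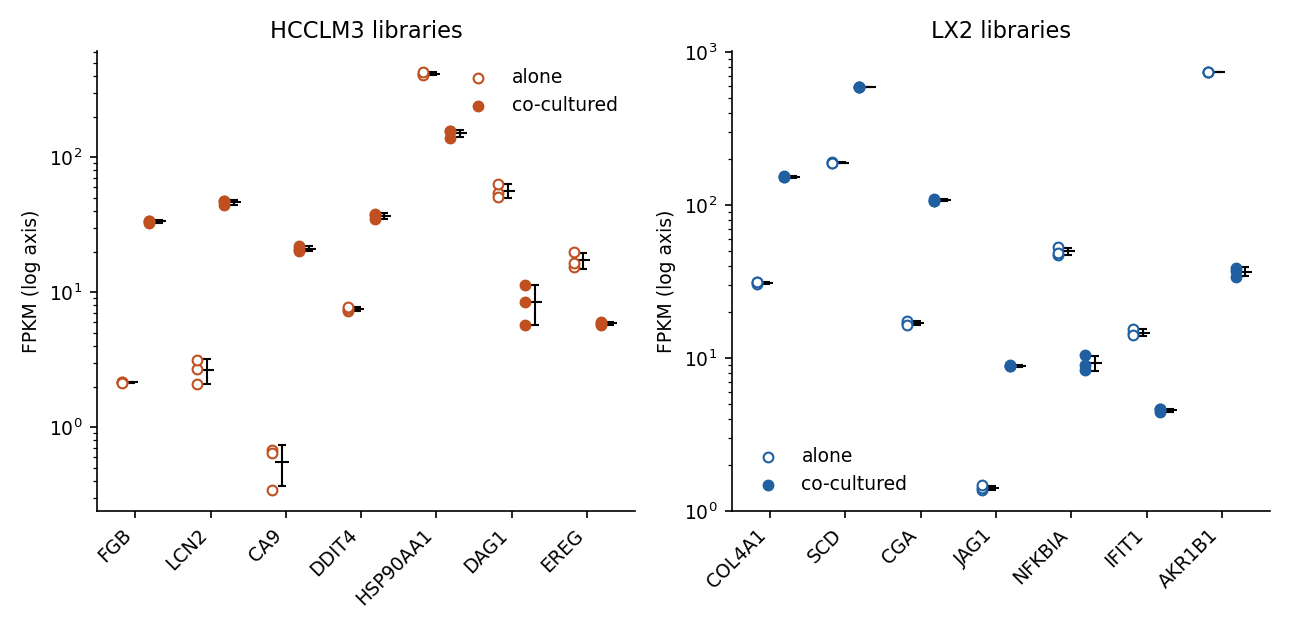
FPKM on a log axis in each library of 7 genes in HCCLM3 (left) and 7 in LX2 (right), open points alone and filled points co-cultured, with the mean ± SD of 3 libraries as black bars. In HCCLM3 the 3 co-cultured libraries lie above the 3 alone for FGB (2.16 and 33.4 FPKM) and below them for HSP90AA1 (416 and 150 FPKM), and in LX2 they lie above for COL4A1 (31.2 and 153 FPKM) and below for AKR1B1 (745 and 36.7 FPKM).

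The second comparison asked how growth with HCCLM3 changed the line given as LX2 in the labels. In LX2 with HCCLM3, the lists of the ATF4 and amino acid response and of cholesterol synthesis were higher and that of the type I interferon response was lower, and these 3 calls held with an estimated correlation. The list of replication-dependent histones was lower by camera, a call that did not hold there. AKR1B1 (ENSG00000085662, chromosome 7, 134442356 to 134459284), aldose reductase, which makes the osmolyte sorbitol, stood at 745 ± 2.36 FPKM alone and 36.7 ± 2.52 FPKM in co-culture (SD, n = 3; log2 fold change -4.37, SE 0.056; edgeR adjusted p = 2.66e-07), a fall of 20.7-fold. COL4A1 (ENSG00000187498, chromosome 13, 110148963 to 110307157), a basement membrane collagen, rose 4.82-fold, from 31.2 ± 0.506 to 153 ± 1.63 FPKM. CGA (ENSG00000135346, chromosome 6, 87085498 to 87095106), the alpha chain of glycoprotein hormones, rose 6.23-fold, from 16.9 ± 0.495 to 108 ± 1.47 FPKM.

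Of 19671 genes tested in LX2, 3020 rose and 3261 fell, 6281 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). On library totals without TMM factors 3322 rose and 2911 fell, and with limma on log2(FPKM + 1) 2725 and 2669, so which direction holds more genes depends on the scaling and test. The 8 largest rises were RHOV (2.98), HES4 (2.96), NR4A3 (2.94), SCUBE1 (2.87), CGA (2.64), SLC16A6 (2.63), JAG1 (2.62) and INSIG1 (2.57), with log2 fold changes in parentheses. JAG1 encodes a ligand of Notch receptors and went from 1.41 ± 0.0487 to 8.87 ± 0.0812 FPKM, and HES4 went from 7.58 ± 0.232 to 60.2 ± 1.68 FPKM. The 8 largest falls were RANBP3L (-8.37), SLC6A12 (-8.26), TNFSF15 (-4.82), AKR1B1 (-4.37), SDR16C5 (-4.22), ETNPPL (-4.21), ZBED6CL (-3.97) and FRMD3 (-3.97). SLC6A12, a betaine transporter gene, went from 10.6 ± 0.319 to 0.0331 ± 0.00768 FPKM. ZBED6CL overlaps LRRC61 on the same strand and its counts are uncertain.

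Of the ATF4 and amino acid response genes, 25 of 26 tested members rose and 0 fell (adjusted over the list alone, 26 and 0) (camera adjusted p = 1.47e-17; adjusted p = 0.0197 with an estimated correlation); SLC7A5 (1.13), STC2 (1.14) and DDIT3 (1.89) rose. The amino acid transporter gene SLC7A5 went from 356 ± 6.71 to 795 ± 7.65 FPKM. Of the cholesterol synthesis and uptake genes, 20 of 24 tested members rose and 0 fell (adjusted over the list alone, 20 and 1), with a median of 1.02 (camera adjusted p = 3.43e-12; adjusted p = 0.0313 with an estimated correlation); HMGCS1 (1.65), MSMO1 (1.15) and STARD4 (1.01) rose. Of the fatty acid and triglyceride genes, 12 of 27 tested members rose and 4 fell (adjusted over the list alone, 13 and 5): SCD (1.62), FASN (1.25) and PDK4 (1.90) rose (camera adjusted p = 0.0142; adjusted p = 0.131 with an estimated correlation). SCD, the stearoyl-CoA desaturase gene, went from 189 ± 1.31 to 594 ± 2.67 FPKM. Of the hypoxia response genes, 17 of 28 tested members rose and 2 fell (adjusted over the list alone, 18 and 2), with P4HA1 (0.90) and PGK1 (0.34) up (camera adjusted p = 2.24e-05; adjusted p = 0.0551 with an estimated correlation), while VEGFA rose from 15.1 ± 0.226 to 16.7 ± 0.458 FPKM (log2 fold change 0.11), a call that some alternatives did not keep. Of the p53 targets, 10 of 21 tested members rose and 1 fell (adjusted over the list alone, 11 and 1): SESN2 (0.76) and TNFRSF10B (0.35) rose and ZMAT3 (-0.52) fell (camera adjusted p = 0.00373; adjusted p = 0.171 with an estimated correlation).

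Of the type I interferon response genes, 1 of 27 tested members rose and 23 fell (adjusted over the list alone, 1 and 23), with a median of -1.45 (camera adjusted p = 3.01e-14; adjusted p = 0.0313 with an estimated correlation). OAS3 (-2.52), DDX58 (-1.87) and IFIT1 (-1.71) fell, OAS3 from 7.85 ± 0.504 to 1.39 ± 0.117 FPKM. Of the NF-kB targets, 4 of 20 tested members rose and 11 fell (adjusted over the list alone, 4 and 11): C3 (-3.60) and NFKBIA (-2.45) fell and TNFAIP3 (1.24) rose (camera adjusted p = 0.00797; adjusted p = 0.123 with an estimated correlation). NFKBIA, the inhibitor of NF-kB that is itself a target, went from 49.8 ± 2.77 to 9.28 ± 1.08 FPKM. Of the replication-dependent histones, 0 of 17 tested members rose and 12 fell (adjusted over the list alone, 1 and 13), led by H2BC12 (-0.42), H2BC21 (-1.22) and H2BC5 (-1.22) (camera adjusted p = 1.64e-05; adjusted p = 0.0575 with an estimated correlation); these transcripts mostly lack poly(A) tails and were measured here after poly(A) selection. Of the heat shock genes, 1 of 19 tested members rose and 11 fell (adjusted over the list alone, 2 and 11): HSPH1 (-1.34), HSPA1A (-1.49) and HSPA1B (-1.24) fell, the last a near-identical pair (camera adjusted p = 0.000102; adjusted p = 0.123 with an estimated correlation). Of the DNA replication genes, 1 of 32 tested members rose and 17 fell (adjusted over the list alone, 1 and 18), with RFC3 (-0.55), FEN1 (-0.54) and MCM5 (-0.48) down (camera adjusted p = 0.00147; adjusted p = 0.0835 with an estimated correlation). Of the mitosis genes, 3 of 32 tested members rose and 11 fell (adjusted over the list alone, 3 and 12), with BUB1B (-0.60), CDK1 (-0.47) and TOP2A (-0.39) down (camera adjusted p = 0.0230; adjusted p = 0.195 with an estimated correlation), and MKI67 had a log2 fold change of 0.28 (edgeR adjusted p = 0.471).

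Matrix and stellate markers moved in both directions in LX2. Of the extracellular matrix genes, 11 of 27 tested members rose and 9 fell (adjusted over the list alone, 11 and 9) (camera adjusted p = 0.309), and COL4A1 (2.27), COL4A2 (1.11), FN1 (0.75) and COL1A1 (1.44) were among the rises. Of the stellate cell and fibroblast markers, 7 of 17 tested members rose and 4 fell (adjusted over the list alone, 7 and 5) (camera adjusted p = 0.413). The actin gene ACTA2 rose from 1.37 ± 0.0777 to 2.81 ± 0.387 FPKM (edgeR adjusted p = 0.00175). VIM and TGFB1 had log2 fold changes of -0.10 and -0.075 (edgeR adjusted p = 0.477 and 0.0817). COL1A2, ALB and APOA1 had too few counts to be tested. Of the matrix proteases and inhibitors, 7 of 19 tested members rose and 6 fell (adjusted over the list alone, 8 and 7) (camera adjusted p = 0.659): MMP2 (-2.17) and TIMP3 (-0.97) fell and ADAMTS1 (1.32) rose. Of the growth factors and ligands, 9 of 28 tested members rose and 5 fell (adjusted over the list alone, 9 and 5) (camera adjusted p = 0.235), with JAG1 (2.62) and GDF15 (0.88) up and WNT5A (-1.73) down. Hepatoma and progenitor markers did not pass as a list (camera adjusted p = 0.0722), and 8 of 14 tested members rose and 3 fell (adjusted over the list alone, 8 and 3). Of those tested, 2 had 0 counts in LX2 alone, KRT19 and SPP1. In co-culture they stood at 0.158% and 0.977% of their levels in HCCLM3 alone, so their rise cannot be told apart from RNA of HCCLM3. The remaining lists did not pass in LX2 (camera adjusted p): actin cytoskeleton and contractility 0.0584, integrins and adhesion receptors 0.142, stemness genes 0.265, angiogenesis factors 0.289, glycolysis 0.349, NRF2 targets 0.372, hepatocyte markers 0.413, TGF-beta response 0.420, mitochondrially encoded genes 0.420, immediate early genes 0.457, cytosolic ribosomal proteins 0.509, endothelial markers 0.509, epithelial genes 0.509, unfolded protein response 0.557, oxidative phosphorylation 0.750, mesenchymal genes 0.753, YAP targets 0.753, leukocyte markers 0.753, cytokines and chemokines 0.784. Of these, NRF2 targets, endothelial markers, oxidative phosphorylation and YAP targets had a median or mean above 0 with a test pointing down, and the unfolded protein response and mitochondrially encoded genes a median below 0 with a test pointing up. In all, 11 of 35 lists passed in LX2, and with an estimated correlation 3 did: the ATF4, interferon and cholesterol lists.

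Genes of the partner line were counted at low levels in co-cultured libraries. They were chosen for a low level in the same libraries alone that served as baseline, which favours a rise. Genes with no own count could not fall. No equally low genes absent from the partner were set beside them, so the number above 0 does not by itself show RNA of the partner. In HCCLM3 with LX2, genes of LX2 stood at a median of 0.143% of their level in LX2 alone (SD over libraries 0.0438, n = 3; 41 genes, 38 of them above 0). That median moved with the limit on the own level, to 0.294% at under 0.5 FPKM and 0.0653% with no own count (8 genes). In LX2 with HCCLM3, genes of HCCLM3 stood at 0.558% of their level in HCCLM3 alone (SD 0.0629, n = 3; 57 genes, 54 above 0). There the secreted glycoprotein gene SPP1 stood at 0.977%, CEACAM6 at 0.895% and the chemokine gene CXCL5 at 3.12%, the highest of the 57. These levels set values of separate tables side by side. CXCL5, at 0 in each library of LX2 alone, was at least 160.3-fold higher over the co-cultured group.

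The third comparison asked whether co-culture changed the lines differently. Interferon response and NF-kB genes moved up in HCCLM3 relative to LX2, and cholesterol synthesis and amino acid response genes moved down relative to LX2. The amino acid response list did not fall in HCCLM3: its median was 0.19 there and 0.72 in LX2, so it rose less. In the same HCCLM3 libraries granulocyte precursor transcripts went from 4 to 3477 counts over the group and erythroid transcripts from 10 to 23727, and leukocyte markers moved up in the difference as well (median 1.44). The effect differed for 4557 genes, higher in HCCLM3 for 2075 and lower for 2482 (edgeR quasi-likelihood test on the difference, Benjamini-Hochberg adjusted p under 0.05). On library totals without TMM factors 3000 were higher and 1598 lower, and with limma on log2(FPKM + 1) 3120 and 1978. Of the lists, 13 differed (5 higher in HCCLM3 and 8 lower), and with an estimated correlation 5 did. The median difference in log2 fold change was 2.32 for the type I interferon response (27 genes, camera adjusted p = 2.24e-19; adjusted p = 0.00101 with an estimated correlation), 0.87 for NF-kB targets (23 genes, camera adjusted p = 2.81e-07; adjusted p = 0.0235 with an estimated correlation) and 0.82 for angiogenesis factors (23 genes, camera adjusted p = 0.000167; adjusted p = 0.0444 with an estimated correlation). It was -1.34 for cholesterol synthesis and uptake (24 genes, camera adjusted p = 2.24e-19; adjusted p = 0.000232 with an estimated correlation) and -0.46 for the ATF4 and amino acid response (26 genes, camera adjusted p = 0.000167; adjusted p = 0.0166 with an estimated correlation). The other lists that differed were growth factors and ligands, hepatoma and progenitor markers, fatty acid metabolism, mitochondrially encoded genes, immediate early genes, leukocyte markers, glycolysis and the hypoxia response (camera adjusted p = 0.00554, 0.00845, 0.0174, 0.0174, 0.0212, 0.0466, 0.0479 and 0.0479), and with an estimated correlation none of these 8 calls held. For the hypoxia response (-0.076) and the extracellular matrix (-0.017) the median lay below 0 and the test pointed up. For endothelial markers, matrix proteases, epithelial genes, heat shock, YAP targets and oxidative phosphorylation the median lay above 0 and the test, which did not pass, pointed down. With genes at 0 in a group set to their bound, the median was 2.32 for interferon and 1.25 for NF-kB targets. Of the 8 genes named for the difference, AKR1B1, SLC16A6, BCAM, GALNT2, SLCO4A1 and TPD52L1 were counted in both lines. AKR1B1 had a log2 fold change of -0.13 in HCCLM3 and -4.37 in LX2, and the transporter gene SLC16A6 of -1.12 and 2.63 (edgeR adjusted p of the difference = 4.44e-09 and 2.15e-09).

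**Figure D3:**
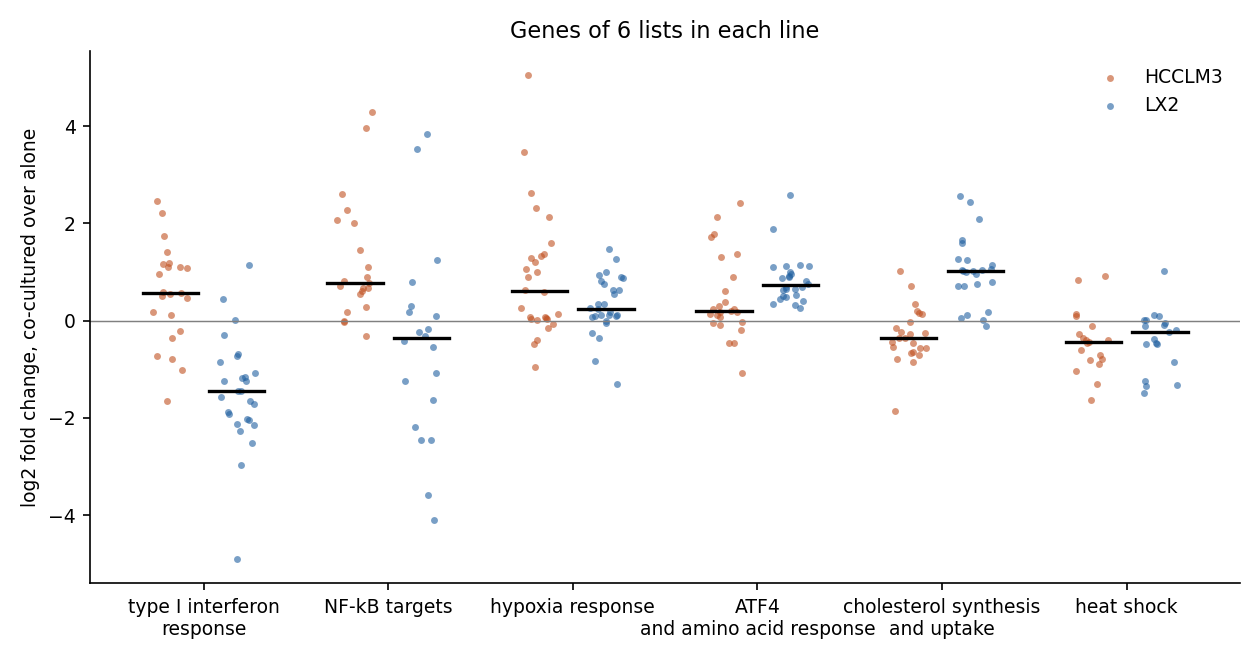
Log2 fold change, co-cultured over alone, of each tested gene of 6 fixed lists in HCCLM3 and LX2, 1 point per gene, with the list median as a black bar and genes at 0 in a group drawn at their bound. The median of the interferon list lies at 0.57 in HCCLM3 and -1.45 in LX2, and that of the cholesterol list at -0.36 in HCCLM3 and 1.02 in LX2.

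Calls shared by the lines were more than independent lists would give. Among 16155 genes tested in both, 425 rose in both, where 265 are given by n1 × n2 / N, and 597 fell in both, where 366 are. Opposite calls were close to that number, with 307 up in HCCLM3 and down in LX2 (293) and 347 the other way (331). Across genes, which are not independent replicates, Spearman's rho of the fold changes was 0.117. Among genes of at least 5 FPKM in 3 libraries, most of this excess was lost: 242 rose in both, where 196 are given, 263 fell in both, where 216 are, and rho was 0.031. On library totals without TMM factors, 721 rose and 279 fell in both. Without HCCLM3 with LX2 replicate 3, 217 rose and 344 fell in both.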

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

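Every test of an explanation here was chosen after the result it bears on was seen, as were the lists of blood, prostate, muscle and neuron genes; the difference between lines was planned.

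The effect of co-culture differed between the lines by a test of the difference itself for 4557 genes. For the named genes, the difference in log2 fold change, HCCLM3 minus LX2, was -3.79 for SLC16A6, 4.21 for AKR1B1, 2.28 for TPD52L1, 3.15 for BCAM, -2.05 for GALNT2 and 2.52 for SLCO4A1. TPD52L1 and SLCO4A1 fell 3.88-fold and 6.60-fold in LX2, BCAM rose 5.19-fold in HCCLM3 and GALNT2 rose 3.21-fold in LX2. CEACAM6 and SPP1 had 0 counts in LX2 alone, so their fitted differences of -14.11 and -11.43 are no measured size: in LX2 they were at least 759-fold and 243-fold higher over the co-cultured group, at 3.36 and 1.36 FPKM. These are 0.895% and 0.977% of their levels in HCCLM3 alone, near the 0.558% of partner transcripts, so no rise in LX2 cells is shown, and in HCCLM3 both fell (log2 fold changes -1.62 and -0.59).

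The lists that differed had median differences of 2.32 for the type I interferon response, -1.34 for cholesterol synthesis and uptake, 0.87 for NF-kB targets, -0.46 for the ATF4 and amino acid response, 0.82 for angiogenesis factors, -0.54 for growth factors and ligands, -0.29 for hepatoma and progenitor markers, -0.26 for fatty acid and triglyceride metabolism, -0.28 for mitochondrially encoded genes, -0.25 for immediate early genes, 1.44 for leukocyte markers, -0.29 for glycolysis and -0.076 for the hypoxia response, whose test pointed up. Only the first 5 passed with an estimated correlation. With genes at 0 in a group at their bound, the medians of NF-kB targets, growth factors and hepatoma markers were 1.25, -0.44 and -0.22.

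Other splits of the libraries were fitted in the same way. The 10 splits of 6 libraries cannot give a share under 0.05, so for the counts within a line chance was not assessed: in HCCLM3 3924 genes passed for the real groups and at most 5 for another split, with 18 and at most 9 lists, and in LX2 6281 and at most 3 genes, with 11 and at most 4 lists. In each of these 4 counts, 1 split, the real one, was as large. For the difference, of 100 drawn splits within the lines, 2 gave as many genes as the real 4557, the real one included, a share under 0.05, so chance can be excluded for that count only against no effect in either line. These splits do not test equal effects in both lines, which is left to the test of each gene, nor chance between cultures, since replicates may be technical. The highest of the others, 5551, kept the real groups of HCCLM3 and exchanged those of LX2, so it measures the sum of both effects. For the lists of the difference chance cannot be excluded: 14 of 100 splits gave 13 or more, with up to 17, and each of the 13 others kept the real groups of at least 1 line. Where neither line kept its real groups, at most 11 lists and 4 genes passed.

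The first pattern is blood and marrow transcripts in HCCLM3 with LX2. Erythroid genes had 10 counts over HCCLM3 alone and 23727 over HCCLM3 with LX2, and in LX2 with HCCLM3 their counts were 1.42% of those in HCCLM3 with LX2, which argues against RNA of LX2 cells, though they also went from 47 counts over LX2 alone to 336 over LX2 with HCCLM3. RNA of blood or marrow cells in these libraries may be the source: of 17 erythroid and granulocyte genes not seen before the lists were written, 7 went from near 0 to at least 10 counts in every co-cultured library (Fisher's exact test, two-sided, p = 1.49e-14), against 0 of 13 muscle and neuron genes. Blood or marrow RNA would not bring the prostate epithelium genes, of which 3 of 5 appeared in the same libraries. That list was written after genes such as KLK3 were seen, so its p-value is no independent evidence (Fisher's exact test, adjusted p = 9.83e-07). That co-culture turned the blood and marrow genes on in HCCLM3 cells stays open, since all 3 co-cultured libraries hold the genes and the group cannot be told apart from the source of the RNA. Uneven transcripts were not confined to co-culture: COL1A2 had 0, 0 and 502 counts in HCCLM3 alone and 0, 320 and 853 in HCCLM3 with LX2. In LX2 alone it had 0 counts in each library.

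The second pattern is that interferon and cholesterol genes moved apart in the lines. Dilution of LX2 RNA by HCCLM3 RNA is argued against: a mix of both lines' levels alone, with 0.809% HCCLM3 RNA (the third quartile of partner transcripts), would change the median by a log2 of -0.010 for 27 interferon genes and -0.00016 for 24 cholesterol genes, against -1.43 and 1.05 measured in FPKM. The scaling of libraries is also argued against: the smaller of both median differences was 1.02 under any setting run, against a shift of all genes of at most 0.17. Whether RNA of blood cells moved the interferon genes of HCCLM3 with LX2 was not tested. In LX2 the interferon list fell by a median log2 of -1.45, with 23 of 27 tested members down. That fall was measured within LX2 libraries, so blood RNA in HCCLM3 libraries does not bear on it. In HCCLM3 the list rose by a median of 0.57, a call that did not hold with an estimated correlation. What HCCLM3 cells add to the difference between the lines stays open.

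The third pattern is that osmolyte genes fell in LX2 with HCCLM3: AKR1B1, SLC6A12 and the inositol transporter gene SLC5A3, the last singled out after its values were seen (log2 fold change -3.43). The same mix would change these 3 genes by a median of -0.011, against -4.34 measured in FPKM, so the tables argue against dilution. AKR1B1 stood at 228 FPKM in HCCLM3 alone and 36.7 FPKM in LX2 with HCCLM3, a level that no share of HCCLM3 RNA would give. Whether the osmotic response fell as a set cannot be told: 6 other genes of it had a median log2 fold change of -0.19 (SD 0.88), 2 fell and 1 rose, SGK1 by 1.34.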

How the results depend on the processing

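The tests with limma on log2(FPKM + 1) as designed, DESeq2, library totals without TMM factors, the lists of the difference and the left-out libraries for the overlap were chosen after seeing the data; the other alternatives were planned, and the cause of the changes below was not tested unless stated.

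The gene counts fell with stricter rules by construction. In HCCLM3, 1093 genes (828 up and 265 down) had also an absolute log2 fold change of at least 1, 1413 (572 and 841) an adjusted p under 0.01, and 2177 passed among genes of at least 5 FPKM in 3 libraries; in LX2 these were 1493 (872 and 621), 3639 (1714 and 1925) and 3546. Leaving out single libraries gave 1971 to 3067 genes in HCCLM3, 4982 to 5218 in LX2 and 3672 to 4534 for the difference. In HCCLM3 the count was 2344 without co-cultured replicate 1, 2591 without replicate 2 and 1971 without replicate 3. The list counts moved more: HCCLM3 had 0 lists with an estimated correlation, 8 with limma at each pseudocount and variance model, 9 at 5 FPKM and 11 after quantile normalization; LX2 had 3 with an estimated correlation and 29 with fry, which tests a list by itself; the difference had 5 with an estimated correlation and 7 at pseudocounts of 0.1 and 0.01. Left-out libraries gave 17 to 20 lists in HCCLM3, 11 to 13 in LX2 and 10 to 14 for the difference.

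Reversed directions were confined to 3 lists: ribosomal proteins and oxidative phosphorylation in HCCLM3 turned up after quantile normalization (limma and camera adjusted p = 0.0444 and 0.0359), and hepatocyte markers in the difference turned up with limma on log2(FPKM + 1) at each variance model (0.0259) and after quantile normalization (0.00549). As reported, none of these lists passed (camera adjusted p = 0.479, 0.929 and 0.999).

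The overlap of calls was 242 up and 263 down at 5 FPKM (196 and 216 for independent lists, ratios of 1.24 and 1.22), 721 and 279 without TMM factors, and 322 and 316 down with limma at pseudocounts of 1 and 0.1; left-out libraries gave 217 to 377 up and 344 to 503 down, lowest without HCCLM3 with LX2 replicate 3. Without HCCLM3 with LX2 replicates 1 and 2, 272 and 274 rose in both, and without replicate 1 391 fell. The ratios to independent lists were 1.61 to 1.78 up and 1.64 to 1.76 down with left-out libraries. They were 1.46 up and 1.76 down without TMM factors, and 1.48 and 1.47 down with limma at pseudocounts of 1 and 0.1. Partner transcripts in HCCLM3 libraries were 0.294% with an own level under 0.5 FPKM and 0.0653% (8 genes) with no own count, and in LX2 libraries 0.684% with no own count; left-out libraries gave 0.126% to 0.195% in HCCLM3 (0.188% without HCCLM3 alone replicate 3 and 0.195% without HCCLM3 with LX2 replicate 1) and 0.495% to 0.595% in LX2 (0.495% without LX2 with HCCLM3 replicate 2).

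Whether the replicate numbers pair the libraries was not settled. Same-numbered libraries correlated at 0.017, 0.045 and 0.023 in HCCLM3, where 6 of 6 correlated best with their own number, a hint from the data only. In LX2 they correlated at -0.039, 0.011 and -0.041, and 1 of 6 correlated best with its own number. With the replicate block, 3315 genes passed in HCCLM3, 4795 in LX2 and 4471 for the difference, with 17, 12 and 10 lists.

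Of single genes and lists, 3824 comparisons with an alternative other than a left-out library kept direction and call, 180 lost and 37 gained the call; with left-out libraries these were 2254, 88 and 16. In simulated data few 1.5-fold changes were recovered, but far fewer genes were changed there than were called here, which makes the adjusted threshold stricter. Smaller effects may be missed here, by a share that was not measured. With limma 3440 genes passed in HCCLM3 and with DESeq2 4989.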

Other observations

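The lists below were added after seeing the data, and each gene named in this part was singled out after its values were seen.

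Of genes with at most 3 counts in each library of HCCLM3 alone, 100 of 37425 (0.267%) had at least 10 counts in each library of HCCLM3 with LX2. Among them were 11 of 17 erythroid genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 16 tests, adjusted p = 2.74e-24), 13 of 17 granulocyte precursor genes (5.93e-30), 3 of 5 prostate epithelium genes (9.83e-07) and 1 of 8 B and plasma cell genes (0.0847). None of 6 T and NK cell, 8 muscle and 5 neuron genes appeared, and no gene of the osmotic response was near 0 alone. Genes such as MPO, HBB and KLK3 had been seen before the lists were written, so these p-values are no independent evidence. In LX2 with HCCLM3 0 genes of these 8 lists appeared, where 76 of 34489 genes did, genes missing from the table of LX2 being read as 0 counts and included, while erythroid counts went from 47 over LX2 alone to 336. The prostate genes KLK3 and PRAC1 had 73, 84 and 50 and 43, 26 and 58 counts in HCCLM3 with LX2, and HOXB13 49, 53 and 23. LX2 alone held 67, 105 and 32 counts of KLK3, and HOXB13 had 296 to 547 counts in each LX2 library. In HCCLM3 with LX2 both therefore stood far above the median of 0.143% measured for genes of LX2 there.

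Genes of LX2 also appeared in HCCLM3 with LX2. CGA, with 0 counts in each library of HCCLM3 alone and 2528 to 2629 in LX2 alone, had 100, 104 and 149 counts, and RNF182 23, 27 and 38. CGA stood there at a mean of 0.731 FPKM, against 16.9 FPKM in LX2 alone and 108 FPKM in LX2 with HCCLM3. Against LX2 alone it too lay far above the median of 0.143%, and its share of the co-cultured level was smaller. RNF182 stood at 0.294% of its level in LX2 alone. In LX2 with HCCLM3, FGB had 24, 8 and 8 counts after 0 in each library alone, and CES1 346, 313 and 279.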
